A study of Mus musculus with 6 samples.

How the data were processed

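Small RNA of c-kit+ cardiac progenitor cells was sequenced. These are heart cells that carry the receptor tyrosine kinase c-kit on their surface, isolated from digested wild-type mouse hearts by magnetic sorting with an antibody to c-kit. The labels give 3 control libraries with 0 hours of hypoxia and 3 libraries of cells cultured for 12 hours under hypoxia, and call each group's libraries biological replicates. Their treatment field names hypoxia for the control samples too, so the groups were taken from the sample titles and times. The labels do not say whether these came from separate animals or cultures, so p-values measure the spread between these libraries, which may be partly technical. The oxygen level is not given in the sources used here. Unless the control cells, labelled 0 hours, were also cultured for 12 hours, time in culture cannot be told apart from hypoxia. The extraction protocol in the labels speaks of RNA from exosomes (small secreted vesicles), whereas the design text of the series speaks of RNA from the cells. The values are called those of the cells here, and this point was not settled.

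Each of 2 tables held raw read counts, deposited by the authors as whole numbers with 1 column per library, for 1978 known mature miRNAs and for 838 predicted miRNAs. The submitters' processing notes name bcl2fastq 2.0, DESeq2 and the mouse build mm10, with no role or order. The aligner, the counting program, the miRNA annotation release and the treatment of reads that match several miRNAs are not given in the sources used here. Without that, 42 known miRNAs whose counts lay within 1% of another miRNA's in every library (30 pairs, such as miR-199a-3p and miR-199b-3p) were read as sharing reads, and their separate values are uncertain. No mature name occurred more than once, so the planned merging of repeated names had nothing to merge.

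Columns were headed by the digit 0 or 1 and a letter, A, B or C. The digit 0 was read as the 0 hours of the control labels, and the digit 1, as the only other one, as the 12 hours of hypoxia. Every direction below rests on that reading. The letters could not be matched to the replicate numbers of the sample titles, so libraries are named by group and letter. Whether same-lettered libraries belong together was checked before calls were compared, by correlating over the tested miRNAs the deviations of each library's log2 CPM from its group mean. The same-letter correlations were 0.52 for A, 0.43 for B and 0.28 for C, and every library correlated best with its own letter. Unlike-letter correlations ran from -0.44 to 0.12, the highest being that of control C with hypoxia B. By the rule fixed for this check (every same-letter correlation over 0.1) the letters paired the libraries, though that 0.12 also lay over the limit. The pairing therefore comes from the column names and the values, not from the labels, and a fit with the letter as a block was added after the data were seen.

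Known miRNA totals ran from 12285970 to 16975987 counts per library, and predicted miRNA totals from 2510 to 4278. The 15 pairs of libraries were compared by chi-square over all miRNAs. The smallest ratio of chi-square to its degrees of freedom was 156, so no library was a copy of another within counting noise. Shares of a library's counts are given with exact Clopper-Pearson 95% intervals, which cover counting error only, since PCR copies are not independent molecules.

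Counts were analysed in R 4.3.3 with edgeR 4.0.16. Rows were filtered with filterByExpr, which left 619 known miRNAs, libraries were scaled by TMM, and hypoxia was tested against control by the quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. CPM denotes counts scaled to a common library size with TMM factors. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. The 34 predicted miRNAs past the filter were fitted together with the known ones, using the known miRNAs' library sizes, and adjusted among themselves. Shares and totals were compared by two-sided exact permutation tests, which for 3 libraries against 3 cannot give a p below 0.1, and the most abundant share also within same-lettered pairs by an exact sign-flip test, added after the data were seen.

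A set of 18 lists was fixed beforehand. They were miR-210, hypoxia-regulated miRNAs from the literature, the miR-17-92 cluster with its paralogs, the miR-15/16, let-7, miR-34, miR-29 and miR-30 families, the miR-23-27-24 clusters, markers of cardiomyocytes, of fibroblasts and smooth muscle, of endothelium, of blood cells, of epithelium, and of neural tissue and liver, the pluripotency clusters, the Dlk1-Dio3 imprinted cluster and the Sfmbt2 cluster. The 15 lists with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, and again with an estimated correlation. Camera asks whether the members of a list differ from the other tested miRNAs. Fry of limma, which asks whether a list's members differ between the groups without regard to other miRNAs, was run beside it. The miRNAs named were chosen by a rule fixed at the same time. It takes both miR-210 arms, the 10 highest and 10 lowest log2 fold changes past the threshold with a mean of at least 10 CPM and no overlap between groups, the 3 smallest p per direction where fewer pass, the 5 most abundant miRNAs, up to 3 most abundant members of each list, and 2 predicted miRNAs per direction. Any other miRNA named was chosen after its values were seen.

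The alternatives fixed before the data were examined were other scalings (DESeq2 size factors, upper quartile, library size only), no filter or a 10 CPM filter, DESeq2 1.42.0, limma-voom, an added fold-change limit, an estimated correlation, other library sizes for the predicted miRNAs, other numbers of miRNAs and another denominator for the share of the most abundant ones, and leaving out each library in turn. Added later were the letter block with its variants, merging miRNAs that share reads, thinning to the smallest library, library sizes without the 2 most abundant miRNAs, and the hypoxia list without miR-210.

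Genome positions are those of GENCODE M21 on GRCm38, the assembly that mm10 denotes. Of the 1978 known names, 1847 (93.4%) matched an annotated miRNA gene. Host genes were read on the same strand only, so a miRNA antisense to a gene is called intergenic. They were sought among protein-coding, lincRNA, processed-transcript and antisense genes that contain the whole hairpin, and not among other gene types. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

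The procedures were tested on simulated counts drawn from the libraries' means and sizes. For known miRNAs, edgeR was run on 609, of which 99 were changed by 1 on the log2 scale and 94 by 2. It recovered 56.6% and 96.8% of these, with 8 false calls among 155. With so many changed, the adjusted threshold is easier to pass, so recovery where few miRNAs change may be lower. With the letter block, run on 601 miRNAs with simulated letter effects, edgeR recovered 79.8% and 97.9%, with 0 false calls among 172. Without the block it recovered 54.5% and 94.7%. The letter effects were put into these draws, so the gain from the block was built in. For predicted miRNAs, run on 31, edgeR recovered 33.3% of 6 changed by 1 and 100% of 4 changed by 2. In 20 draws without any change, edgeR made a call in 0 draws without the block and in 1 draw with it. Camera called a shifted list of 10 in 18 of 20 draws, and 0 of 280 others. These lists were random miRNAs drawn independently of each other. The draws therefore do not show how often camera at the preset correlation calls lists whose members vary together.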

Results

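The series profiled miRNAs in mouse c-kit+ cardiac progenitor cells kept as controls or cultured under hypoxia for 12 hours, with 3 libraries in each group. Its title names miR-210-3p, a miRNA known as a target of the hypoxia-inducible transcription factors, and the effect of that miRNA on these cells under ischemia and hypoxia. The comparison of the deposited counts asks which miRNAs differed between cells with and without the hypoxic culture.

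Known miRNAs gave 12285970, 14526041 and 15166638 counts in control libraries A, B and C, and 15596688, 16975987 and 13170756 in hypoxia libraries A, B and C. The difference in totals between the groups did not exceed the spread between libraries (n = 3 each, two-sided exact permutation test, p = 0.4, smallest possible 0.1). Between 959 and 1023 known miRNAs were detected per library, with means of 979 ± 21.7 in control and 1015 ± 9.29 in hypoxia (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). Within same-lettered pairs the hypoxia library had 59 (A), 47 (B) and 3 (C) more detected miRNAs (exact sign-flip permutation p = 0.25, the smallest possible), and it was the deeper one in pairs A and B and the shallower one in pair C. A count of 0 allowed a level of up to 0.244 CPM in the shallowest library (3 counts of its total). Log2 CPM of any 2 libraries correlated across miRNAs with Pearson's r from 0.977 to 0.991, where miRNAs are not independent replicates.

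The libraries were dominated by miR-21a-5p, a miRNA widely induced in injured and proliferating cells, and miR-126a-3p, a miRNA of endothelial cells encoded within the Egfl7 gene. On average miR-21a-5p took 29.4% and miR-126a-3p 22.1% of known miRNA counts. The next were let-7i-5p with 4.99%, let-7f-5p with 3.53% and miR-143-3p, a miRNA of smooth muscle cells and fibroblasts, with 3.15%. None of these 5 passed the test between groups. For miR-21a-5p the level was 307505 ± 46386 CPM in control and 282939 ± 29459 CPM in hypoxia (SD, n = 3 each), a log2 fold change of -0.12 (SE 0.14). The corresponding log2 fold changes were -0.09 for miR-126a-3p, -0.17 for let-7i-5p, 0.00 for let-7f-5p and -0.10 for miR-143-3p. The 10 most abundant miRNAs together held 74.3% ± 1.11 of counts in control and 72.3% ± 1.31 in hypoxia (SD, n = 3 each), a difference of -1.93 percentage points (two-sided exact permutation test, p = 0.3, smallest possible 0.1). Within same-lettered pairs the share was lower in hypoxia by similar amounts, with differences of -2.22 for A, -1.70 for B and -1.88 for C (SD 0.265), which exceeded the spread between pairs, although an exact sign-flip permutation test of 3 pairs cannot go below p = 0.25, the value it gave.

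miR-210-3p was 2.28-fold higher in the hypoxia libraries. Its level was 232 ± 56.8 CPM in control and 528 ± 128 CPM in hypoxia (SD, n = 3 each), and the lowest hypoxia library (440 CPM, from 6068 counts) lay above the highest control library (296 CPM, from 3848 counts). The log2 fold change was 1.19 (SE 0.25), and within the letters it was 1.85 for A, 0.66 for B and 1.06 for C. The other arm of the same hairpin, miR-210-5p, stood at 4.36 ± 1.4 CPM in control and 13.2 ± 8.65 CPM in hypoxia (SD, n = 3 each), a log2 fold change of 1.59 (SE 0.47) that rested largely on hypoxia library A, with 385 counts against 135 and 111 in B and C. Both arms come from Mir210, at chromosome 7, 141221384 to 141221493 on the minus strand of GRCm38, with no host gene of the types sought on that strand.

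Adjusted over all 619 tested miRNAs, edgeR's quasi-likelihood test did not call either miR-210 arm (adjusted p = 0.65 for both), while both passed when adjusted over the list alone. Without the expression filter the same test called both (edgeR adjusted p = 0.0018 each). For miR-210-3p the log2 fold change and SE hardly moved (1.16, SE 0.24), so that call does not reflect a clearer difference between the libraries. It depends on including the miRNAs that the filter removes. With the letter as a block, edgeR called miR-210-3p (log2 fold change 1.19, SE 0.20, adjusted p = 0.024) but not miR-210-5p (1.42, SE 0.40, adjusted p = 0.082), and DESeq2 without a block also called miR-210-3p (adjusted p = 0.019). Over 23 alternative settings miR-210-3p stayed above 0 in all 23 and passed in 7, with adjusted p from 2.1e-08 to 0.99. The blocked call was not kept without pair A (log2 fold change 0.86, edgeR adjusted p = 0.054) or without pair C (1.25, edgeR adjusted p = 0.47).

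**Figure D1:**
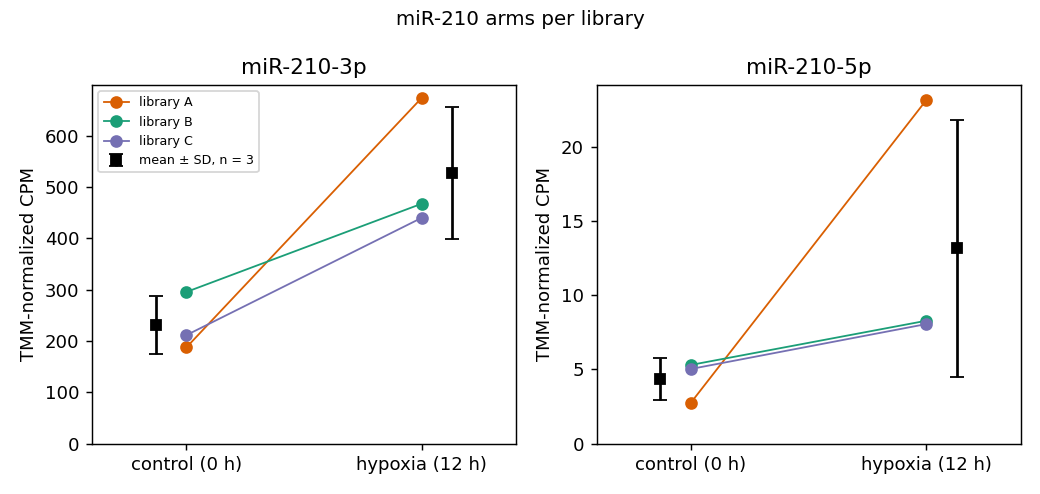
Levels of miR-210-3p (left) and miR-210-5p (right) in TMM-normalized CPM on axes that start at 0, for control (0 h) and hypoxia (12 h) libraries; lines join libraries with the same letter, and black squares with bars give the mean ± SD of 3 libraries. Each hypoxia library lay above its same-lettered control for both arms, and hypoxia library A was the highest for both (674 and 23.1 CPM).

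Across all known miRNAs, edgeR called 0 of 619 without a block. At an unadjusted p under 0.05 there were 42 miRNAs, 25 higher and 17 lower in hypoxia, where chance alone gives 31.0. On the same miRNAs limma-voom called 0 (43 at that p), and DESeq2, on all 1322 miRNAs with a count, called 1 (45 at that p). An even spread of p over the 1322 would give 66.1, but miRNAs with only a few counts can hardly reach that p. The 45 therefore cannot be read as fewer than chance gives. The 2 groups did not overlap for 80 miRNAs (12.9%), where chance gives 10%. In edgeR without the block, the miRNAs with the smallest p and at least 10 CPM, none of which passed there, were in the upward direction miR-210-3p, miR-503-5p and miR-362-3p. In the downward direction they were miR-671-3p, miR-149-5p and miR-125b-1-3p.

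With the letter as a block, edgeR called 14 miRNAs, 6 higher and 8 lower in hypoxia, and 132 had an unadjusted p under 0.05. The 6 that rose in that fit were miR-210-3p, miR-503-5p, miR-362-3p, miR-188-5p, miR-369-3p and miR-138-5p. Besides miR-210-3p the largest rise was that of miR-503-5p, a repressor of cell cycle genes, from 78.9 ± 21.1 to 160 ± 52.0 CPM (SD, n = 3 each), with a blocked log2 fold change of 1.00 (SE 0.12, edgeR adjusted p = 0.0072). It is encoded on chromosome X, 53053984 to 53054054 on the minus strand, with no host gene of the types sought on that strand. Levels of miR-362-3p went from 44.4 ± 12.4 to 80.1 ± 15.6 CPM and those of miR-188-5p from 11.9 ± 3.55 to 19.6 ± 6.07 CPM (SD, n = 3 each), with blocked log2 fold changes of 0.87 (SE 0.16) and 0.71 (SE 0.13). Both lie in introns of Clcn5 on chromosome X, miR-362 at 7241982 to 7242046 and miR-188 at 7247989 to 7248056. miR-138-5p rose by 0.61 (SE 0.12) and miR-369-3p by 0.63 (SE 0.13) on the log2 scale.

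Of the 8 miRNAs that fell with the letter as a block, miR-671-3p fell most, from 49.2 ± 8.33 to 25.4 ± 7.27 CPM (SD, n = 3 each), a blocked log2 fold change of -0.97 (SE 0.13, edgeR adjusted p = 0.0083). Its gene lies in an exon of Chpf2 on chromosome 5, 24592114 to 24592211. The most abundant was miR-125b-1-3p, from 765 ± 100.1 to 489 ± 127 CPM (SD, n = 3 each), with a blocked log2 fold change of -0.67 (SE 0.12). miR-149-5p, in an intron of Gpc1 on chromosome 1 (92850378 to 92850443), went from 21.2 ± 2.79 to 12.5 ± 2.11 CPM (SD, n = 3 each), a blocked log2 fold change of -0.77 (SE 0.13). The others were miR-370-3p (-0.79), miR-543-3p (-0.67), let-7c-1-3p (-0.64), miR-495-3p (-0.60) and miR-129-5p (-0.59). Among the 14, miR-369-3p, miR-370-3p, miR-495-3p and miR-543-3p belong to the Dlk1-Dio3 imprinted cluster of chromosome 12, and 1 of these 4 rose while 3 fell. The 8 called miRNAs outside the fixed naming rule (miR-188-5p, miR-138-5p, miR-369-3p, miR-370-3p, miR-543-3p, let-7c-1-3p, miR-495-3p and miR-129-5p) were named after their values were seen.

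All 14 were also called by DESeq2 with the letter block, and 11 of them had an unadjusted p under 0.05 in edgeR without the block. The blocked count was 0 without pair A, 23 without pair B and 0 without pair C, and with scaling to library size only it was 55, of which 44 were higher and 11 lower.

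**Figure D2:**
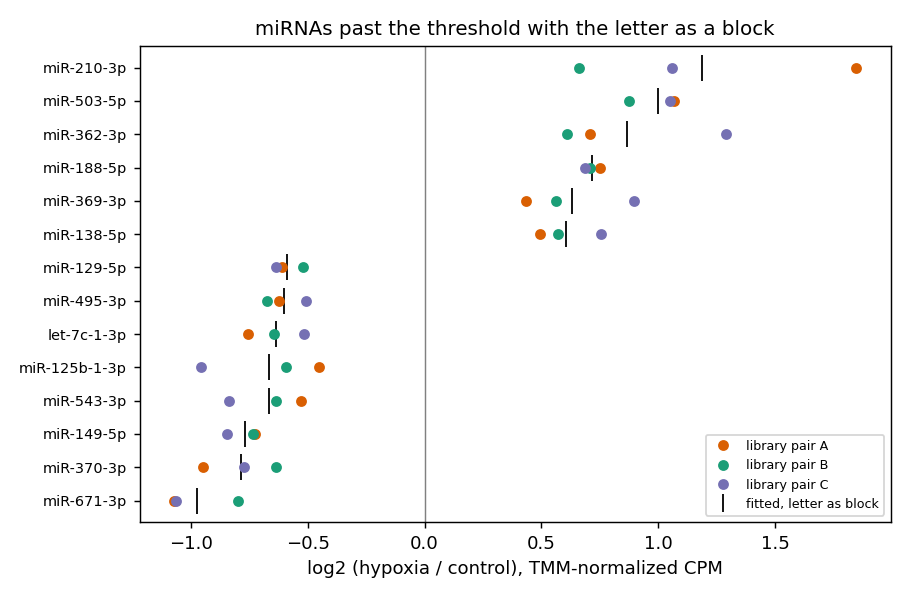
The 14 miRNAs past the threshold in edgeR with the letter as a block, with log2 of hypoxia over control (TMM-normalized CPM) on the horizontal axis; coloured points are the 3 same-lettered library pairs and black ticks the fitted log2 fold changes. All 3 pairs of every miRNA lie on the side of its fitted value, which runs from -0.97 for miR-671-3p to 1.19 for miR-210-3p.

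Among the fixed lists, camera called 5 of 15 without a block, 4 upward and 1 downward, and none of the 5 held with an estimated correlation. Fry, planned beside camera, called no list. For these 5 its adjusted p ran from 0.15 to 0.64 without the block and from 0.13 to 0.25 with it. No single miRNA in these lists passed edgeR over all tested miRNAs without the block. With the block, 132 of all 619 tested miRNAs had an unadjusted p under 0.05 in edgeR. Passes over a list alone with the block are therefore not particular to these lists, and they were not adjusted across lists. Several lists share members, such as miR-322-5p (miR-15/16 and hypoxia-regulated) and the miR-23, miR-24 and miR-27 arms (clusters and hypoxia-regulated).

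All 6 members of the miR-15/16 family, which restrains cell cycle progression, had positive log2 fold changes, with a median of 0.38. The family rose as a list (camera adjusted p = 0.029, and adjusted p = 0.33 with an estimated correlation), and did so with the letter block at the preset correlation (adjusted p = 0.013, and adjusted p = 0.56 with an estimated correlation). The call was lost without control A, hypoxia B or hypoxia C (camera adjusted p = 0.071, 0.053 and 0.099) and, with the block, without pair B (adjusted p = 0.066). Levels of miR-16-5p were 1168 ± 173 CPM in control and 1557 ± 225 in hypoxia, those of miR-322-5p 148 ± 38.2 and 210 ± 55.5, and those of miR-195a-5p 176 ± 33.0 and 208 ± 52.4 (SD, n = 3 each). Adjusted over the list alone, 0 of 6 passed edgeR without the block and 4 with it (miR-15a-5p, miR-15b-5p, miR-16-5p and miR-322-5p).

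The miR-29 family, which represses collagens and other matrix proteins, also had 6 of 6 positive members, with a median of 0.30 (camera adjusted p = 0.029, and adjusted p = 0.33 with an estimated correlation). With the letter block the list did not pass (adjusted p = 0.064), and without the block it did not pass without control A, control C, hypoxia B or hypoxia C (adjusted p = 0.079, 0.077, 0.11 and 0.099). miR-29a-3p stood at 6844 ± 525 CPM in control and 8522 ± 1453 in hypoxia, miR-29b-3p at 4255 ± 1576 and 6221 ± 1142, and miR-29c-3p at 47.3 ± 6.60 and 73.8 ± 15.8 (SD, n = 3 each). For these 3 arms the differences came from pairs B and C (log2 from 0.47 to 1.30), while in pair A they were -0.12, -0.24 and 0.04. Adjusted over the list alone, 0 of 6 passed without the block and 1, miR-29c-3p, with it.

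The hypoxia-regulated list had 14 of 20 members above 0, with a median of 0.08 (camera adjusted p = 0.031, and adjusted p = 0.33 with an estimated correlation). Without the 2 miR-210 arms it did not pass (camera adjusted p = 0.28), nor did the whole list with the letter block (adjusted p = 0.13). Without the block it was also lost without control A, control C, hypoxia A or hypoxia B (adjusted p = 0.29, 0.077, 0.058 and 0.11). Its most abundant members gave log2 fold changes of -0.12 (miR-21a-5p), -0.07 (miR-26a-5p, SE 0.13) and 0.05 (miR-27b-3p, SE 0.14). Adjusted over the list alone, miR-210-3p passed without the block, and 4 passed with it (both miR-210 arms, miR-107-3p and miR-322-5p).

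The miR-23-27-24 clusters fell as a list, with 9 of 11 members below 0 and a median of -0.24 (camera adjusted p = 0.031, and adjusted p = 0.72 with an estimated correlation). With the letter block it passed at the preset correlation (adjusted p = 0.021, and adjusted p = 0.56 with an estimated correlation), but not without pair A or pair B (adjusted p = 0.057 and 0.14). Without the block the call was lost with upper-quartile scaling (adjusted p = 0.052) and without control B, control C or hypoxia A (adjusted p = 0.42, 0.077 and 0.42). The most abundant arms gave small values, 0.05 for miR-27b-3p, -0.12 for miR-24-3p (SE 0.17) and -0.12 for miR-27a-3p (SE 0.20). Adjusted over the list alone, 0 of 11 passed without the block and 3 with it, the 5p arms of miR-23a, miR-23b and miR-27a, which lay at 4.69, 11.9 and 315 CPM in control and 2.67, 7.62 and 232 CPM in hypoxia.

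Of 8 cardiomyocyte markers 5 passed the expression filter, and all 5 lay above 0, with a median of 0.52 (camera adjusted p = 0.031, and adjusted p = 0.72 with an estimated correlation). The list passed with the letter block at the preset correlation (camera adjusted p = 0.017, and adjusted p = 0.56 with an estimated correlation). The call was lost without control A, control C or hypoxia B (adjusted p = 0.37, 0.11 and 0.37) and, with the block, without pair A (adjusted p = 0.099). Their levels were low. miR-1a-3p stood at 98.4 ± 47.2 CPM in control and 119 ± 27.9 in hypoxia, miR-206-3p, a skeletal muscle miRNA, at 93.6 ± 19.3 and 104 ± 23.9, and miR-133a-3p at 9.63 ± 3.51 and 14.2 ± 6.39 (SD, n = 3 each). Adjusted over the list alone, 0 of 5 passed without the block and 2 with it, miR-133a-3p and miR-133b-3p.

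The number of lists called depended on single libraries. It was 3 without control A, 1 without control C, 1 without hypoxia B and 3 without hypoxia C, against 5 with all 6. The Dlk1-Dio3 list was called upward without control A (camera adjusted p = 8.7e-06) and downward without control B or hypoxia A (adjusted p = 0.0034 and 1.5e-06), and the fibroblast and smooth muscle list upward without control A (adjusted p = 0.021).

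**Figure D3:**
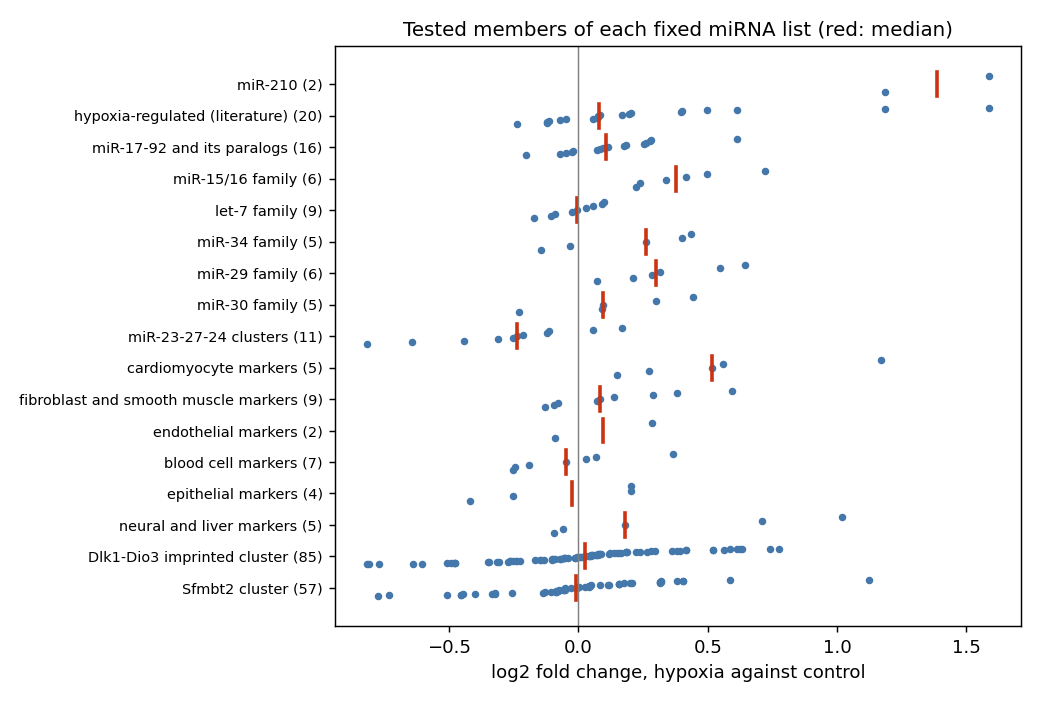
Log2 fold changes (hypoxia against control, edgeR without a block) of the tested members of 17 fixed lists, 1 point per miRNA, with the median in red and the number of tested members in brackets. All tested members of the miR-15/16, miR-29 and cardiomyocyte lists lie above 0, while the let-7 members lie around a median of 0.00.

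The remaining lists did not pass camera with all 6 libraries, with or without the letter block. The miR-17-92 cluster and its paralogs, which promote proliferation, had 11 of 16 members above 0 (median 0.11), among them miR-20a-5p at 0.08, with miR-25-3p at -0.02 and miR-92a-3p at -0.20. The let-7 family, which restrains proliferation, had 4 of 9 above 0 (median 0.00), with let-7c-5p at -0.03. The miR-34 family, a set of p53 targets, had 3 of 5 above 0 (median 0.26), with miR-34a-5p at 0.40 (SE 0.19), miR-34b-5p at 0.44 (SE 0.23) and miR-34c-5p at 0.26 (SE 0.21). The miR-30 family had 4 of 5 above 0 (median 0.09), with miR-30a-5p at 0.09, miR-30c-5p at 0.30 and miR-30d-5p at -0.23. The Sfmbt2 cluster, a rodent array in an intron of that gene, had 27 of 57 above 0 (median -0.01). Its most abundant members were miR-467a-5p and miR-467b-5p, which share reads (log2 fold change -0.32), and miR-669c-5p (0.08). The 13 pluripotency cluster miRNAs had 0 members past the expression filter. Adjusted over each list alone, 0 members of these lists passed without the block, and with it miR-34a-5p, miR-34b-5p and miR-30b-5p did.

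Markers of other cell types were measured alongside. Fibroblast and smooth muscle markers had 6 of 9 members above 0 (median 0.08), with miR-199a-3p, which shares reads with miR-199b-3p, at 0.38 (SE 0.32) and miR-199a-5p at 0.07. The 2 endothelial arms went opposite ways, miR-126a-3p at -0.09 and miR-126a-5p at 0.28 (SE 0.16). Blood cell markers had 3 of 7 above 0 (median -0.05), with miR-146a-5p at -0.24, miR-155-5p at -0.05 and miR-486a-5p, which shares reads with miR-486b-5p, at -0.25. Epithelial markers had 2 of 4 above 0 (median -0.03, mean -0.07, while camera gave the upward direction), and miR-200a-3p, miR-200b-3p and miR-200c-3p stayed below 3 CPM in both group means. Neural and liver markers had 3 of 5 above 0 (median 0.18), with miR-128-3p at -0.10, miR-122-5p at -0.06 and miR-9-5p at 0.18. None of these lists was called with all 6 libraries, and the fibroblast and smooth muscle list was called only when control A was left out. Adjusted over each list alone 0 members passed without the block, while with it miR-199a-3p, miR-199b-5p, miR-126a-5p and miR-9-3p did.

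The Dlk1-Dio3 imprinted cluster had 47 of 85 tested members above 0 (median 0.02, while camera gave the downward direction without the block) and was not called with all 6 libraries. Adjusted over the list alone, 0 members passed without the block, and 3 higher and 3 lower did with it. Its most abundant members were miR-127-3p (log2 fold change -0.09, SE 0.37), miR-379-5p (-0.04, SE 0.40) and miR-434-5p (-0.26, SE 0.36), whose errors were larger than those of miRNAs of similar abundance such as miR-25-3p (SE 0.16).

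Libraries also differed by letter within each group, and A was set against B and C only after the values were seen. In both groups 82 of the 85 Dlk1-Dio3 members were higher in library A than in the mean of B and C, with median log2 differences of 1.07 in control and 1.01 in hypoxia. miR-127-3p stood at 4263, 1954 and 2414 CPM in control A, B and C and at 4166, 1972 and 1956 CPM in hypoxia A, B and C. All 9 fibroblast and smooth muscle markers were likewise higher in A in both groups (medians 0.92 and 0.80), as for miR-143-3p with 49636, 25883 and 21694 CPM in control and 41052, 28249 and 21695 CPM in hypoxia. As lists both were higher in A (camera with group as a covariate, adjusted p = 1.9e-45 for Dlk1-Dio3 and 1.4e-05 for the fibroblast and smooth muscle markers), and neither held with an estimated correlation (adjusted p = 0.12 and adjusted p = 0.16). The miR-23-27-24 list was lower in A (adjusted p = 0.0019, and adjusted p = 0.80 with an estimated correlation), with 10 of 11 members lower in A in both groups.

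**Figure D4:**
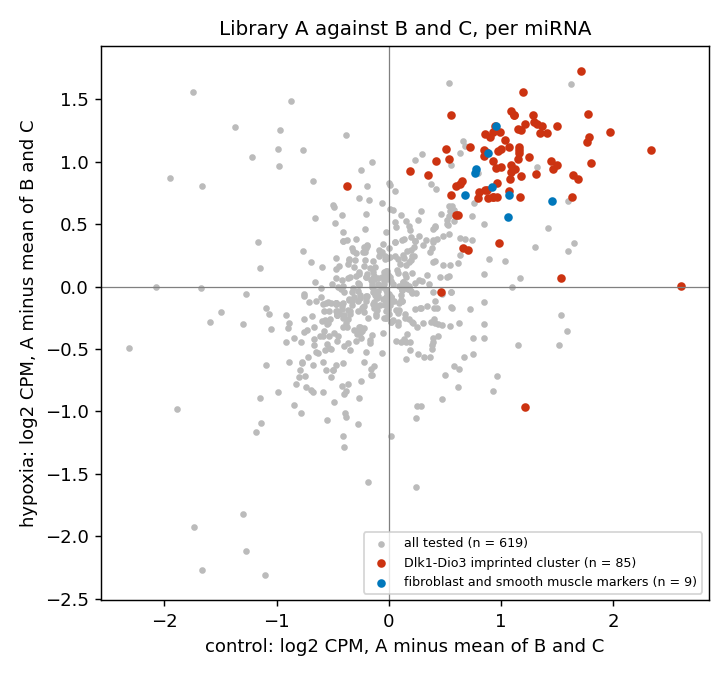
Difference in log2 CPM between library A and the mean of libraries B and C, in control (horizontal) and in hypoxia (vertical), 1 point per tested miRNA (619, grey), with the Dlk1-Dio3 cluster (85) in red and the fibroblast and smooth muscle markers (9) in blue. Of the cluster 82 members, and of the markers all 9, lie above 0 on both axes.

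The predicted miRNAs held 0.0191% to 0.0252% of the counts per library (exact 95% intervals from 0.0183 to 0.0198% in hypoxia C, and from 0.0244 to 0.0260% in hypoxia B). edgeR called 0 of 34 (1 at an unadjusted p under 0.05), as it did with the letter block (1 at that p), and DESeq2 called 0 (2 at that p). The smallest p values were those of chr2_23942 (2.03 ± 0.352 CPM in control and 0.917 ± 0.381 in hypoxia, log2 fold change -1.12, SE 0.42) and chr6_37064 (-0.80, SE 0.42) in the downward direction. In the upward direction they were those of chr11_6715 (0.38, SE 0.34) and chr12_9892 (0.35, SE 0.45).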

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

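The tests with the letter as a block, of the share within pairs, with merged or thinned counts, without the 2 most abundant miRNAs and without miR-210 were chosen after the result was seen. The planned block by replicate number was not run, since the columns carry letters, and the planned summing of repeated names was not run, since no name repeats. The direction of miR-210-3p held in all 23 alternatives. Without the filter, edgeR called 4 known miRNAs, all higher in hypoxia, and camera 0 lists. The 4 were miR-210-3p (log2 fold change 1.16), miR-210-5p, miR-96-3p and miR-503-5p, and their calls depend on including the miRNAs that the filter removes. DESeq2 called 1 (miR-210-3p, 1.18). With an estimated correlation 0 lists passed. Leaving out each library in turn gave 0 known miRNAs each time, 1 to 5 lists, and log2 fold changes of miR-210-3p from 0.97 to 1.38. The replicate block by letter gave 14 known miRNAs, 3 lists (0 with an estimated correlation), 0 predicted miRNAs and 1.19 for miR-210-3p. With that block, DESeq2 gave 36 known miRNAs and 1.18, DESeq2 size factors 13 and 1.18, and library size only 55 and 1.25. Also with the block, leaving out pair A gave 0 known miRNAs and 2 lists, pair B 23, 1.42 for miR-210-3p and 1 list, and pair C 0 and 3 lists. The 5 called lists kept their directions in every alternative that changed their test, and passed in 10 of 17 (miR-15/16 and cardiomyocyte markers), 8 of 17 (miR-23-27-24), 7 of 17 (miR-29) and 6 of 18 (hypoxia-regulated). Uncalled lists did turn, such as let-7 with library size only, fibroblast and smooth muscle without control B or hypoxia A, and Dlk1-Dio3 between left-out libraries. The cause of these shifts was not tested. The share of the 10 most abundant miRNAs (p = 0.25 by an exact sign-flip test of the lettered pairs, the smallest possible) and the predicted miRNAs moved to no other side in any alternative. For single named miRNAs, 1116 of 1188 values stayed as reported, 44 passed where they had not, 28 moved by more than 1 SE without passing and 0 passed in the opposite direction. Median log2 fold changes over all tested miRNAs were 0.01 with TMM, 0.00 with DESeq2 size factors or upper quartile, and 0.08 with library size only. The predicted miRNAs had only 2510 to 4278 counts per library, and few passed the filter (34 of 838).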

Other observations

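In this part, the tests of the libraries' letters, of miR-210 within letters and of the X-linked clusters, and the miRNAs named in the next paragraph, were chosen after the result was seen.

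Neighbouring hairpins of the miR-183/96/182 cluster on chromosome 6 (30165918 to 30169737), a group best known from sensory cells, had 5 of 5 tested arms above 0, with a median log2 fold change of 0.20 (camera over 34 genomic clusters, adjusted p = 0.084, and adjusted p = 0.91 with an estimated correlation). Its rare arm miR-96-3p had 0, 3 and 1 counts in control A, B and C against 34, 19 and 9 in hypoxia A, B and C. edgeR did not call it with the filter (adjusted p = 0.65) and called it without the filter (adjusted p = 0.0019). That call too depends on including the miRNAs that the filter removes. The abundant arms differed little, with miR-182-5p at 169 ± 59.6 CPM in control and 173 ± 44.2 in hypoxia and miR-183-5p at 136 ± 29.6 and 149 ± 27.4 (SD, n = 3 each). miR-30b-5p stood at 279 ± 22.0 CPM in control and 379 ± 21.4 in hypoxia, and miR-107-3p, encoded within a pantothenate kinase gene, at 126 ± 2.59 and 167 ± 6.50 (SD, n = 3 each). Neither passed edgeR over all tested miRNAs (adjusted p = 0.66 and 0.72, and 0.060 and 0.082 with the letter block).

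The letter of a library went with more miRNAs than the group did. A letter effect passed edgeR for 160 of 619 miRNAs, 70 of them in the Dlk1-Dio3 cluster, and 103 of the 160 were higher and 52 lower in A in both groups. The cluster holds miRNAs of the maternally expressed transcripts Meg3, Rian and Mirg, with examples in miR-379-5p (1969, 850 and 913 CPM in control A, B and C, 1862, 906 and 866 in hypoxia) and miR-411-5p (1409, 555 and 633, then 1303, 640 and 628). miR-214-3p, a fibroblast marker, stood at 353, 165 and 223 CPM in control and 414, 165 and 235 in hypoxia. Blood cell markers were mixed, with 3 of 7 higher and 3 lower in A in both groups. Of these, miR-155-5p was higher in A (894, 598 and 621 CPM in control, 1013, 493 and 539 in hypoxia), whereas miR-150-5p of mature lymphocytes was lower, with 7.53 CPM in control A and 5.77 in hypoxia A and between 17.6 and 21.3 in the other 4 libraries.

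Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 0 known miRNAs and the highest other 2, so all 10 gave as many, and for predicted miRNAs all 10 gave 0. It gave 5 lists and the highest other 5, with 3 of 10 splits as high. The other splits that reached 5 kept both A libraries together, and those that part every same-lettered pair gave 2, 1 and 2 lists, again too few to give a share under 0.05. Among the 4 splits that part every same-lettered pair, the real one gave 14 known miRNAs with the block and the highest other 0, so 1 of 4 gave as many. Splits that kept both A libraries together gave 61, 99, 78 and 134 miRNAs at an unadjusted p under 0.05, against 42 for the real split. The others gave 4 to 18, including 18 and 16 for the pair of splits that kept the B and the C libraries together but parted A, which points to the A libraries standing apart.

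For the higher miR-210 arms in hypoxia, a few dominant miRNAs were weighed as the cause. The 2 most abundant held 52.2% ± 2.05 of known counts in control and 50.8% ± 1.46 in hypoxia (SD, n = 3 each). Shares this close leave little room for a 2.28-fold rise of miR-210-3p, which argues against that cause. For the same reason, library sizes without these 2 could hardly have moved its log2 fold change (1.16, SE 0.25), so that fit adds little. Thinning to the smallest library (1.18, SE 0.25) keeps the expected share of each miRNA and so could not decide on library depth. The totals argue against depth for both arms. Hypoxia C was shallower than control B and C (13170756 against 14526041 and 15166638 known counts). It still held more counts of miR-210-3p (6068 against 3848 and 3322) and of miR-210-5p (111 against 69 and 79). Hypoxia A (15596688) was close in depth to control C, with 674 against 212 CPM of miR-210-3p. The hypoxic culture itself would give 6 of 6 differences above 0 over the 2 arms and 3 letters, the count found. It could not have come out otherwise, since the groups did not overlap in either arm, and any other cause of the rise would give it too. The hypoxic culture as the cause remains a hypothesis, since the test was chosen with the values in view. Time in culture may differ between the groups too, as the labels give the controls 0 hours. In both arms pair A gave the largest difference (1.85 and 3.07 on the log2 scale). A swap of the column digits would turn the direction and was not testable here.

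For the letters, depth as the cause is argued against by the totals, since control A was the shallowest of its group while hypoxia A ranked 2 of 3. A higher share of fibroblasts or smooth muscle cells in the A libraries is a candidate explanation, as 9 of 9 marker miRNAs were higher in A in both groups, of which miR-143-3p and miR-199a-3p were the most abundant. That explanation was drawn from these same values, and the list did not hold with an estimated correlation (camera adjusted p = 0.16). The progenitor cells themselves may express these miRNAs. All 9 passed the expression filter, but a small share of other cells could bring them past it too. Selection for c-kit should remove fibroblasts, though the purity of the sorted cells was not measured here. A culture, animal or preparation day shared by a letter stays open, since the labels record none that the 160 miRNAs with a letter effect could be set against.

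Arms of 2 X-linked clusters, Mir450b to Mir322 (53047997 to 53054349) and the Clcn5 intron cluster (7237683 to 7248497), included miR-503-5p, miR-362-3p and miR-188-5p. The median log2 fold changes of all tested arms were small, 0.04 in the first cluster (from -0.44 to 1.02) and 0.11 in the second (from -0.26 to 0.85). Whether these clusters rise as units under hypoxia cannot be told apart from single arms rising, as camera with an estimated correlation gave adjusted p of up to 0.94 and 12 of 19 arms were above 0.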
